A study of Mus musculus with 16 samples.

How the data were processed

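RNA from flow-sorted mouse cardiac fibroblasts was measured in 16 libraries, 1 column each, in 3 deposited tables. RNA was taken with a micro-scale kit and amplified as cDNA with the SMART-seq v4 low-input method, per the labels' protocols. The tools kallisto and DESeq2 and the build GRCm38 are named in the submitters' processing notes; their versions and the gene annotation are not given in the sources used here. The deposited values are a normalized signal: estimated counts per gene after division by normalization factors, made by the authors separately for each table, as the values and the names of the deposited tables show. They are not whole numbers and sum to between 27814940 and 40970391 per library. Low values (0.5 to 6) of genes with 1 transcript lay on whole steps of 0.900 to 1.16 per read, within 0.03 of a step, in 40.7% to 93.1% of cases, but those of all genes did so in only 35.6% to 67.5%. Whole reads were therefore not recovered, and no count model was fitted.

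The tables list 18634 (loss, uninjured), 17303 (loss, injured) and 17730 (gain, injured) genes. No columns were identical, and Pearson's r of log2 values between libraries of a table was 0.945 to 0.984. The tables do not name all genes alike or hold them all at like levels, which was noticed after the data were examined. Over the 16135 genes listed in all 3, control means were compared, and a gene was counted where the other 2 tables lay within 2-fold of each other and this table lay over 8-fold from their mean on the log2 scale. The injured loss table was lower for 204 and higher for 6 genes, the gain table for 2 and 0, and the uninjured table, which differs in injury too, for 108 and 12. The injured loss table also lacks 144 symbols that exceed 1000 normalized counts in both other tables, and it holds 7 members of the oxidative phosphorylation list under newer symbols. These genes stayed in the planned tests, and the counts of genes and lists in injured loss, the interaction count and the correlations with the other comparisons were recomputed without those at unlike levels; overlaps and gene sets were not.

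Groups were taken from the sample labels. Genes with a mean of at least 10 in a table were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, two-sided, Benjamini-Hochberg adjusted p below 0.05), with only the 2 groups of a comparison in each fit and no covariate. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The difference of the loss effect with and without injury was an interaction contrast over the 4 loss groups. Gene lists fixed before the data were examined (37 lists, 962 genes) were tested where at least 5 members were tested, with camera at a preset correlation of 0.01 and the same variance trend, with an estimated correlation, and with fry, which asks whether the genes of a set move one way on balance. Correlations and overlaps of fold changes between comparisons share no library, and the expected overlap is that of independent calls. Chromosome positions are those of GENCODE vM21 on GRCm38, matched by symbol for 89.9% to 91.1% of tested genes.

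Named genes followed a rule set before the data were examined: a fixed panel of 14 genes, in each comparison up to 8 named genes with the largest rise and 8 with the largest fall among those past the threshold with a mean of at least 50 and no overlap between groups, and up to 4 members of each list with the smallest p. Any gene outside it is said to be chosen after its values were seen, and some genes that the rule took are not reported here. On simulated data with known changes, the tests recovered 53.1% of genes changed by 1 and 82.1% of those changed by 2 on the log2 scale in the uninjured loss comparison (15199 genes), 34.4% and 63.2% in the injured loss comparison (14555 genes), 44.9% and 71.7% in the gain comparison (15118 genes) and 30.9% and 65.2% for the interaction (13831 genes). False calls numbered 1 of 130, 0 of 93, 5 of 120 and 8 of 97 calls in the same order. The simulated genes varied independently, without correlation between genes or effects shared by a library. These rates need not hold for the real data. Alternatives varied the pseudocount, the filter, the scaling, the variance model, the library weights, the replicate block and the gene set test, and left out each library in turn. Comparing levels of an uninjured with an injured group was left out, because their tables were normalized separately.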

Results

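Cardiac fibroblasts were sorted by flow cytometry from the hearts of mice aged 8 to 12 weeks, through an EGFP lineage reporter switched on by Cre, and their RNA was sequenced in 16 libraries of 6 groups. Tcf21 encodes a basic helix-loop-helix transcription factor of the fibroblast lineage. In the loss arm a floxed Tcf21 was deleted with Tcf21-MerCreMer, and mice with the Cre alone were controls. Without injury there were 3 deleted and 3 control libraries, taken 2 weeks after tamoxifen. After 1 week of angiotensin II and phenylephrine infusion, which drives fibrosis, there were 2 deleted and 3 control libraries. In the gain arm TCF21 was expressed from a Col1a1-TCF21 transgene switched on by Pdgfra-CreERT, and 2 gain and 3 Cre-only control libraries were taken after the same infusion. The normalized counts of a library summed to between 27814940 and 40970391. Ddx3y, a Y-linked gene, lay between 2152 and 4454 in all 16 libraries. Xist, which the loss tables do not list, reached at most 11.4 in the gain table. Each comparison lies within 1 of 3 separately normalized tables, so levels set side by side across tables were not put on a common scale. No label states which libraries came from separate animals, so p-values measure only the spread between these libraries.

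The targeted gene moved as labelled in every library. Tcf21 (gene ENSMUSG00000045680, chromosome 10, 22817281 to 22820174, minus strand, GRCm38) was 5.61-fold lower after deletion in uninjured hearts (1405 ± 271 against 7805 ± 288 normalized counts, SD, n = 3 and 3). The deleted libraries held 1244, 1254 and 1718, and the controls 7825, 8081 and 7507. After infusion it was 8.98-fold lower (222 ± 51.9 against 2042 ± 684 normalized counts, SD, n = 2 and 3), with 258 and 185 in the deleted libraries and 2814, 1802 and 1509.8 in the controls. In the gain arm it was 2.44-fold higher (14161 ± 932 against 5813 ± 585 normalized counts, SD, n = 2 and 3), with 14819.6 and 13502 in the gain libraries and 6058, 5145 and 6235 in the controls. The labels do not say how far transcripts of the transgene count towards Tcf21. The limma adjusted p was 4.22e-05, 0.00494 and 0.00446 in these 3 comparisons.

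**Figure D1:**
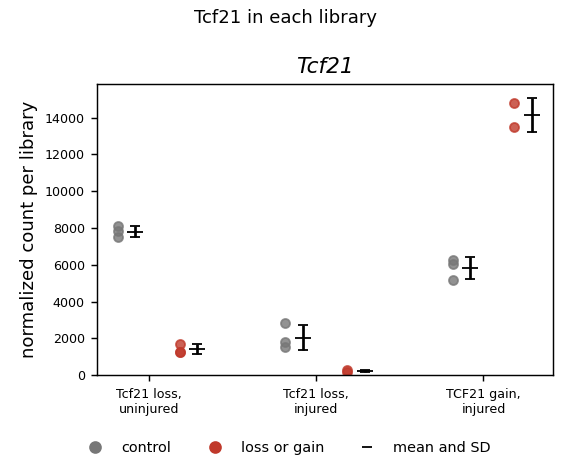
Normalized counts of Tcf21 in each library (points), with the mean and SD of each group beside them; grey, control, and red, loss or gain of TCF21. The groups do not overlap in any of the 3 comparisons, which were normalized separately.

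The comparison without injury asks what loss of Tcf21 does in resting fibroblasts. On the list of activated fibroblast and matrifibrocyte genes, 3 of 23 tested members rose, 0 fell and 20 did not pass (adjusted over the list alone, 7 rose and 1 fell). The list rose at a median of 0.50 on the log2 scale (camera adjusted p = 0.000532, and adjusted p = 0.571 with an estimated correlation), or 0.32 to 0.64 with 1 library left out. Against the control mean, the deleted libraries lay at 0.65, 0.042 and 0.59, and the controls at -0.21, -0.0059 and 0.19. Comp (cartilage oligomeric matrix protein), which is also on the cartilage and bone list, rose 2.14-fold (8046 ± 768 against 3783 ± 551 normalized counts, SD, n = 3 and 3, log2 fold change 1.09, SE 0.118, adjusted p = 0.00319). The secreted Wnt modulator Sfrp2 rose 2.47-fold and the transcription factor Meox1 1.53-fold. The chondrocyte gene Cytl1 rose 2.68-fold and the alkaline phosphatase Alpl 2.20-fold. Of the cartilage and bone genes, 3 of 19 tested members rose and 1 fell (adjusted over the list alone, 3 and 2), and the list was not past camera (adjusted p = 0.228). Elastin (Eln) was 2.504-fold lower (10334 ± 1787 against 25827 ± 3958 normalized counts) and the laminin chain Lama4 was 1.54-fold lower. The elastic fibre genes Fbln5 and Efemp2 rose 1.47-fold and 1.38-fold. Of the matrix glycoproteins and proteoglycans, 2 of 33 tested members rose and 2 fell (adjusted over the list alone, 4 and 4), and the list was not past camera (adjusted p = 0.836). The log2 fold change and its 95% interval were 0.061, -0.21 to 0.33 for Col1a1, 0.33, -0.14 to 0.81 for Postn (periostin) and 0.050, -0.40 to 0.50 for Acta2 (smooth muscle actin), none past the threshold.

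Lists of lipid, energy and protein handling genes passed camera upward in these uninjured fibroblasts with the preset correlation, and none did with an estimated one, where the lowest adjusted p was 0.243. Of the cholesterol biosynthesis genes, 5 of 23 tested members rose, 0 fell and 18 did not pass (adjusted over the list alone, 11 rose and 0 fell), with Stard4, a sterol carrier, 2.99-fold higher and Idi1 2.16-fold higher. This list had a median log2 fold change of 0.53 (camera adjusted p = 1.17e-08, and adjusted p = 0.571 with an estimated correlation), or 0.34 to 0.73 with 1 library left out, the deleted libraries lying at 0.31, 0.95 and 0.42 against the control mean. Of the oxidative phosphorylation genes, 4 of 39 tested members rose, 0 fell and 35 did not pass (adjusted over the list alone, 8 rose and 0 fell). Their shift was small, with a median of 0.19 (camera adjusted p = 2.26e-09, and adjusted p = 0.497 with an estimated correlation), and the complex I gene Ndufa1 rose 1.63-fold. Log2 fold changes ran lower for longer transcripts across all genes of this comparison (Spearman rho -0.143 across genes, which are not independent replicates). Of the unfolded protein response genes, 6 of 30 tested members rose, 0 fell and 24 did not pass (adjusted over the list alone, 14 rose and 1 fell), among them the chaperones Pdia4 (1.87-fold higher) and Calr (1.67-fold higher). Their list gave camera adjusted p = 1.04e-05, and adjusted p = 0.571 with an estimated correlation, and lay at 0.58, 0.17 and 0.12 in the deleted libraries (0.14 to 0.35 with 1 library left out). In collagen processing, 2 of 28 tested members rose, 0 fell and 26 did not pass (adjusted over the list alone, 4 rose and 0 fell), Serpinh1, the collagen chaperone, being 1.58-fold higher (camera adjusted p = 3.82e-05, and adjusted p = 0.243 with an estimated correlation). The glycolysis and hypoxia list rose too, with 5 risen, 0 fallen and 20 of 25 tested members not past the test (adjusted over the list alone, 11 risen and 0 fallen). Aldoa was 1.35-fold and Gapdh 1.35-fold higher (camera adjusted p = 0.000102, and adjusted p = 0.243 with an estimated correlation). The complement genes (median 0.23, camera adjusted p = 0.00475, and adjusted p = 0.571 with an estimated correlation) and the Wnt and BMP pathway genes (median 0.13, camera adjusted p = 0.0202, and adjusted p = 0.571 with an estimated correlation) also rose as lists, though neither passed without deleted library 3 (medians 0.17 and 0.29). Over all such fits the medians were 0.17 to 0.53 and 0.12 to 0.33.

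The mural cell markers, genes of pericytes and smooth muscle, fell as a list, with 0 risen, 4 fallen and 14 of 18 tested members not past the test (adjusted over the list alone, 0 risen and 7 fallen), at camera adjusted p = 3.47e-05, and adjusted p = 0.243 with an estimated correlation. The proteoglycan Cspg4 (NG2) was 3.44-fold lower (226 ± 40.6 against 771 ± 62.5 normalized counts, log2 fold change -1.78, SE 0.169, adjusted p = 0.00137) and the channel subunit Abcc9 1.68-fold lower. Chaperones fell as the heat shock list, with 0 risen, 3 fallen and 14 of 17 tested members not past the test (adjusted over the list alone, 0 risen and 5 fallen), and Hspa8 was 1.58-fold lower (camera adjusted p = 0.00765, and adjusted p = 0.571 with an estimated correlation). The heat shock list was not past camera without deleted library 2 (median -0.11) or 3 (-0.16), its median being -0.42 to -0.11 with 1 library left out. Erythroid and platelet markers lay at 5.13 in deleted library 1 against the control mean, and at 0.27 and -0.93 in the other deleted libraries. Their list was not past camera (camera adjusted p = 0.360, and adjusted p = 0.571 with an estimated correlation). Among cytokine genes Ccl11 (eotaxin) rose 2.14-fold and the alarmin Il33 1.79-fold, while the adhesion molecule Vcam1 was 1.42-fold lower. Of the inflammation genes, 4 of 37 tested members rose and 2 fell (adjusted over the list alone, 5 and 3), and the list was not past camera (adjusted p = 0.104). The interferon-induced Ifi27 rose 1.88-fold and the complement regulator Clu 1.75-fold. The largest changes that the naming rule took included the kinase Pim1 (7.89-fold higher), the stromelysin Mmp3 (10.2-fold lower), xanthine dehydrogenase Xdh (7.82-fold lower) and the GABA receptor subunit Gabra3 (37.4-fold lower, log2 fold change -5.23, or -5.73 to -4.54 with 1 library left out).

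In total, 557 of 15544 tested genes passed limma at adjusted p below 0.05 in the uninjured comparison, 253 higher and 304 lower after deletion. The groups did not overlap for 27.7% of tested genes, where chance gives 10%. The count was 109, 103 and 88 without control 1, 2 and 3, and 891 without deleted library 1, and it was 94 without the variance trend and 949 with library weights. With an estimated correlation 0 of 33 lists passed camera (3 at an unadjusted p below 0.05, lowest adjusted p = 0.243), against 10 with the preset one and 4 by fry. Of 10 splits of these libraries, the real one included, 5 gave as many lists by the preset correlation, at most 12. Of the 46 genes named in the text that passed, 19 passed without each library in turn, as did 7 of the 10 lists. Not past the test in at least 4 of these fits were Aldoa, Aqp1, Clu, Efemp2, Fbln5, Gapdh, Lama4, Meox1, Pi16, Sox9, Zeb1 and, chosen after its values were seen, Hebp2.

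The injured loss comparison asks what loss of the factor does in fibroblasts of an injured heart. On the list of matrix glycoproteins and proteoglycans, 0 of 32 tested members rose, 2 fell and 30 did not pass (adjusted over the list alone, 0 rose and 5 fell). The list fell at a median of -0.34 (camera adjusted p = 5.95e-05, and adjusted p = 0.531 with an estimated correlation), or -0.34 to -0.20 with 1 library left out. Fmod (fibromodulin, a collagen-binding proteoglycan) was 2.66-fold lower (13984 ± 779 against 37714 ± 7369 normalized counts, SD, n = 2 and 3, log2 fold change -1.41, SE 0.178, adjusted p = 0.0236), a call lost in 3 of 5 fits with 1 library left out. Comp held 10801 ± 93.7 against 24228 ± 5488 normalized counts (log2 fold change -1.14, SE 0.186, adjusted p = 0.0534), which missed the threshold. Its log2 fold change was -1.28 to -0.97 with 1 library left out. One of the fallen members of the list, Fbln2, is held at another level in this table than in the others. Its control mean was 1912 here (9.99-fold lower after deletion) and 112573 and 173055 in the uninjured and gain tables. Adamtsl2, an ADAMTS-like matrix protein gene, was 2.10-fold lower. Of the activated fibroblast and matrifibrocyte genes, 0 of 23 tested members rose and 1 fell (adjusted over the list alone, 0 and 2). Their list was not past camera (median 0.24, adjusted p = 0.256). Acta2 was 11373 ± 3741 against 5150.0 ± 2822 normalized counts (log2 fold change and 95% interval 1.25, 0.21 to 2.28, adjusted p = 0.244), which did not pass once adjusted for all genes tested. The corresponding values were 0.24, -0.85 to 1.32 for Postn and 0.42, -0.58 to 1.42 for Col1a1.

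The contractile genes of myofibroblasts rose as a list in injured fibroblasts without Tcf21, with 16 of 23 members above control, though 0 passed on their own, over all genes or adjusted over the list alone. The median was 0.22 (camera adjusted p = 0.00428, and adjusted p = 0.776 with an estimated correlation), and the list was not past camera without control 1 (0.18) or deleted library 2 (0.16). Immediate early genes, which also respond to cell dissociation, fell as a list with a median of -0.47 and 26 of 29 below control (0 passed over all genes and 9 adjusted over the list alone, camera adjusted p = 7.96e-09, and adjusted p = 0.585 with an estimated correlation). Genes of resting cardiac fibroblasts fell as a list, at a median of -0.30, with 0 single members past the test (camera adjusted p = 0.0137, and adjusted p = 0.776 with an estimated correlation). The controls themselves lay at 0.47, -0.075 and -0.47 on this list, and without control 1 or deleted library 2 its median was -0.057 or -0.084 and not past camera. The TGF-beta signalling list fell too, with a median of -0.19 and 0 single members past the test (camera adjusted p = 0.0265, and adjusted p = 0.536 with an estimated correlation), and it was not past camera without control 3 (-0.15), deleted library 1 (-0.16) or deleted library 2 (-0.17). The cholesterol synthesis genes rose as a list at a median of 0.24, with 1 risen, 0 fallen and 21 of 22 tested members not past the test (adjusted over the list alone, 2 risen and 0 fallen), at camera adjusted p = 0.000805, and adjusted p = 0.776 with an estimated correlation. Against the control mean, control 2 lay at 0.44 on this list, above the deleted libraries at 0.23 and 0.33, and the median was 0.15 to 0.41 with 1 library left out. The list of cell cycle genes held Ccnd1 (cyclin D1), 1.89-fold higher, and the replication helicase subunit Mcm6, 2.88-fold lower, at a median of 0.42 (camera adjusted p = 0.0475, and adjusted p = 0.776 with an estimated correlation). Its camera direction reversed without control 1 or without deleted library 2, where the median was 0.034 and 0.025. The CDK inhibitor Cdkn2b rose 1.80-fold. Other lists that rose were those of oxidative phosphorylation (median 0.26, camera adjusted p = 1.39e-08), ribosomal proteins (median 0.24, camera adjusted p = 1.61e-08), the unfolded protein response (median 0.34, camera adjusted p = 4.33e-05), collagen processing (median 0.28, camera adjusted p = 0.000412), glycolysis and hypoxia (median 0.21, camera adjusted p = 0.00761) and the p53 response (median 0.17, camera adjusted p = 0.0109). With an estimated correlation each of these had an adjusted p of at least 0.536. The oxidative phosphorylation list lacked the 7 members that this table names otherwise, and with them its median was 0.25. Without deleted library 2 the unfolded protein response list (median 0.052) and the p53 list (0.091) were not past camera. Nor was the p53 list without control 1 (0.13) or the glycolysis list without deleted library 1 (0.20). With 1 library left out the medians of the ribosomal and collagen processing lists were 0.15 to 0.33 and 0.15 to 0.39. Log2 fold changes ran lower for longer transcripts here too (rho -0.167). No lists matched on length were drawn for this comparison, so a part of length in the oxidative phosphorylation and ribosomal protein lists was not tested.

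Blood cell markers differed between the same groups. The globin gene Hba-a1 was 102 ± 70.5 against 4.64 ± 2.04 normalized counts (log2 fold change 4.06, adjusted p = 0.0380; log2 fold change 3.29 to 4.82 with 1 library left out), and the list of erythroid and platelet markers had a median of 2.96 over 6 members, at 3.92 and 1.91 in the deleted libraries against the control mean (camera adjusted p = 0.00374, and adjusted p = 0.585 with an estimated correlation). Without deleted library 1 this list was not past camera (median 2.37). Myeloid markers fell as a list, at a median of -0.59 (-0.83 to -0.37 with 1 library left out), with 0 risen, 1 fallen and 19 of 20 tested members not past the test (adjusted over the list alone, 0 risen and 4 fallen), and the MHC class II chaperone Cd74 was 4.90-fold lower (camera adjusted p = 0.00163, and adjusted p = 0.536 with an estimated correlation). The largest changes that the naming rule took included the chitinase-like Chi3l1 (7.80-fold higher), the formin Fhod3 (7.75-fold higher), the ER lectin Erlec1 (6.09-fold higher), and Gabra3 and Xdh, 21.7-fold and 11.1-fold lower. Pcdhgb8, H2-Bl, Rpl26 and Ugt1a6b also passed, and each has close relatives or copies that share sequence, so their values are uncertain.

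In total, 135 of 14799 tested genes passed limma in the injured comparison, 48 higher and 87 lower after deletion, and 28.9% of them were unnamed gene models, against 13.6% of tested genes. The count was 47 among named protein-coding genes, 48 without control 2, 42 and 32 without deleted library 1 or 2, 72 without the variance trend and 308 with library weights. With an estimated correlation 0 of 33 lists passed camera (2 at an unadjusted p below 0.05, lowest adjusted p = 0.531), against 16 with the preset one and 0 by fry. Of 10 splits of these libraries, the real one included, 5 gave as many lists by the preset correlation, at most 20. Of the 22 genes named in the text that passed, 7 passed without each library in turn, as did 8 of the 16 lists. Not past the test in at least 4 of these fits were Cd74, Cdkn2b, Hba-a1 and, chosen after its values were seen, Hebp2.

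The gain comparison asks what extra TCF21 does in fibroblasts of an injured heart. Of the activated fibroblast and matrifibrocyte genes, 1 of 23 tested members rose, 7 fell and 15 did not pass (adjusted over the list alone, 1 rose and 15 fell). Fmod, Cilp2 and Chad are members of this list and of the cartilage and bone list. The activated fibroblast and matrifibrocyte list fell at a median of -0.62 (camera adjusted p = 1.58e-07, and adjusted p = 0.512 with an estimated correlation). Fmod was 4.98-fold lower (11242 ± 410.1 against 57191 ± 15058 normalized counts, SD, n = 2 and 3, log2 fold change -2.32, SE 0.200, adjusted p = 0.00446), Comp 3.18-fold lower (9125 ± 3289.7 against 28713 ± 7742 normalized counts, log2 fold change -1.67, SE 0.268, adjusted p = 0.0205, lost in 2 of 5 fits with 1 library left out) and the cartilage matrix genes Cilp2 and Chad 6.13-fold and 5.62-fold lower. Of the cartilage and bone genes, 1 of 23 tested members rose, 6 fell and 16 did not pass (adjusted over the list alone, 2 rose and 9 fell), at camera adjusted p = 0.0105, and adjusted p = 0.517 with an estimated correlation, and the list median was -0.25, or -0.47 to -0.35 with 1 library left out. Itga11, the collagen-binding integrin subunit, was 2.76-fold lower, Col8a2 2.10-fold lower and Timp3 2.53-fold lower, whereas Col18a1 rose 3.38-fold and Adamtsl2 2.64-fold. Of the collagen genes, 1 of 21 tested members rose and 2 fell (adjusted over the list alone, 1 and 2), and the list was not past camera (adjusted p = 0.915). The log2 fold change and its 95% interval were -0.23, -0.96 to 0.49 for Col1a1, 0.054, -0.77 to 0.88 for Postn and 0.24, -0.58 to 1.06 for Acta2, none past the threshold.

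Of the 41 tested cell cycle genes 41 had higher means with TCF21 gain, with a median of 1.25, but 2 passed over all genes (Ccnd1, 2.38-fold higher, and Mcm2, 2.21-fold higher) and 34 adjusted over the list alone (camera adjusted p = 8.52e-16, and adjusted p = 0.517 with an estimated correlation). The controls were spread widely on this list, at 0.72, 0.25 and -0.92 against their mean, and the gain libraries lay at 1.34 and 1.29. Without control 3 the median was 0.81. Myeloid markers also rose as a list, at a median of 0.43, with 0 risen, 1 fallen and 25 of 26 tested members not past the test (adjusted over the list alone, 0 risen and 1 fallen), at camera adjusted p = 0.0424, and adjusted p = 0.766 with an estimated correlation. The gain libraries lay at 0.080 and 0.88 on this list, which was not past camera without control 1 (median 0.39), control 2 (0.46) or gain library 2 (0.080). Immediate early genes fell as a list, with 1 risen, 8 fallen and 20 of 29 tested members not past the test (adjusted over the list alone, 1 risen and 22 fallen). Btg2 was 2.45-fold and Gadd45b 2.24-fold lower, while Egr3 rose 2.62-fold (camera adjusted p = 1.61e-11, and adjusted p = 0.517 with an estimated correlation). Of the inflammation genes, 0 of 38 tested members rose, 5 fell and 33 did not pass (adjusted over the list alone, 1 rose and 11 fell), the chemokine Cxcl1 being 2.61-fold lower and Il33 1.93-fold lower (camera adjusted p = 0.00123, and adjusted p = 0.517 with an estimated correlation).

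Among receptor genes in the gain comparison, Agtr1a, a receptor of the infused angiotensin II, was 2.93-fold lower (93.5 ± 36.8 against 271 ± 69.2 normalized counts, log2 fold change -1.55, SE 0.322, adjusted p = 0.0451) and Adra1a, a receptor for phenylephrine, 7.98-fold lower, while angiotensin-converting enzyme Ace rose 1.68-fold. With 1 library left out these calls were lost in 5 of 5 fits for Agtr1a, 5 of 5 for Adra1a and 4 of 5 for Ace. The list of angiotensin, adrenergic and endothelin receptor genes fell, with 1 risen, 2 fallen and 13 of 16 tested members not past the test (adjusted over the list alone, 1 risen and 7 fallen), by camera adjusted p = 0.0133 and adjusted p = 0.512 with an estimated correlation. Of the Wnt and BMP pathway genes, 1 of 32 tested members rose, 3 fell and 28 did not pass (adjusted over the list alone, 3 rose and 8 fell), with the antagonists Wif1, Chrdl1 and Bmper 5.28-fold, 4.34-fold and 2.91-fold lower and the ligand Gdf6 3.01-fold higher (camera adjusted p = 0.0153, and adjusted p = 0.512 with an estimated correlation). The list median was -0.40, or -0.44 to -0.17 with 1 library left out. Complement genes fell as a list, with 1 risen, 3 fallen and 13 of 17 tested members not past the test (adjusted over the list alone, 1 risen and 9 fallen), and C3 and Clu were 2.69-fold and 3.06-fold lower (camera adjusted p = 0.0176, and adjusted p = 0.512 with an estimated correlation). The resting fibroblast list fell, with 0 risen, 2 fallen and 30 of 32 tested members not past the test (adjusted over the list alone, 0 risen and 3 fallen), at camera adjusted p = 0.00362, and adjusted p = 0.766 with an estimated correlation. The epicardial list fell, with 0 risen, 2 fallen and 3 of 5 tested members not past the test (adjusted over the list alone, 0 risen and 3 fallen), at camera adjusted p = 0.0129, and adjusted p = 0.512 with an estimated correlation. Its 2 fallen members were Clu and C3, which the complement list holds too, and 2 of the 5 lay above control. The unfolded protein response list (camera adjusted p = 0.00123, and adjusted p = 0.512 with an estimated correlation) and the ribosomal protein list (camera adjusted p = 0.00362, and adjusted p = 0.785 with an estimated correlation) rose, with 0 of 31 and 0 of 55 members risen over all genes and 0 and 0 adjusted over the list alone. Without gain library 2 the complement, resting fibroblast and epicardial lists were not past camera (medians -0.24, -0.22 and -1.05). The ribosomal list was not past it without control 3 (0.023) or gain library 1 (0.083). The unfolded protein response median of 0.22 was 0.13 to 0.26 with 1 library left out, and the resting fibroblast median of -0.38 was -0.60 to -0.22. The largest changes included the retinoic acid binding protein Crabp1 (2345 ± 956 against 24.1 ± 22.3 normalized counts, 137-fold higher, log2 fold change 7.10), the ligand Wnt4 (12.4-fold higher), tenomodulin Tnmd (11.9-fold lower), its relative Cnmd (7.95-fold lower) and the cartilage gene Matn3 (6.29-fold lower). With 1 library left out the log2 fold change of Crabp1 was 6.08 to 7.88, with its call lost in 2 of 5 fits, and that of Tnmd, -3.58 with all, was -4.17 to -2.98.

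In total, 637 of 15369 tested genes passed limma in the gain comparison, 242 higher and 395 lower with gain. The count was 222 without control 1, 162 and 124 without gain library 1 or 2 (9 lists past camera without gain library 2), 25 without the variance trend and 1013 with library weights. With an estimated correlation 0 of 34 lists passed camera (2 at an unadjusted p below 0.05, lowest adjusted p = 0.512), against 14 with the preset one and 1 by fry. Of 10 splits of these libraries, the real one included, 4 gave as many lists by the preset correlation, at most 18. Of the 48 genes named in the text that passed, 17 passed without each library in turn, as did 8 of the 14 lists. Not past the test in at least 4 of these fits were Ace, Adra1a, Agtr1a, Matn3, Mcm2, Meox1, Pdlim4 and Srf.

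**Figure D2:**
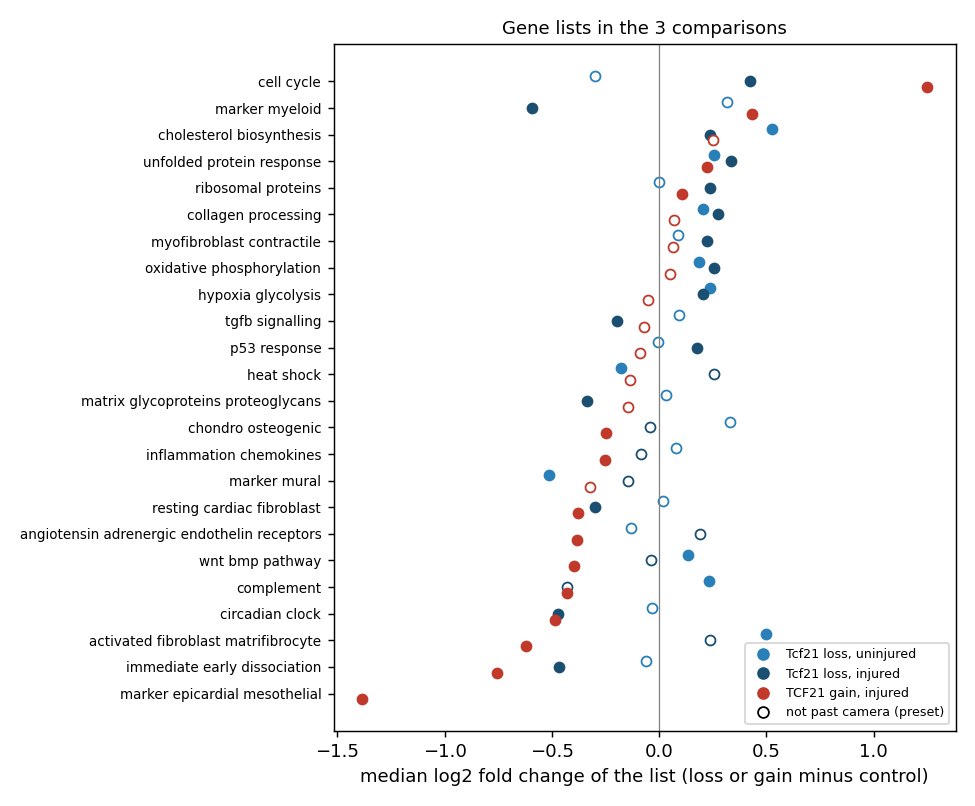
Median log2 fold change of each gene list (x axis) that passed camera with the preset correlation in at least 1 comparison, light blue for loss without and dark blue for loss with injury, and red for gain of TCF21; open circles did not pass in that comparison. The erythroid and platelet list, at 2.96 after loss with injury, lies off the axis and was left out. No list passed with an estimated correlation.

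**Figure D3:**
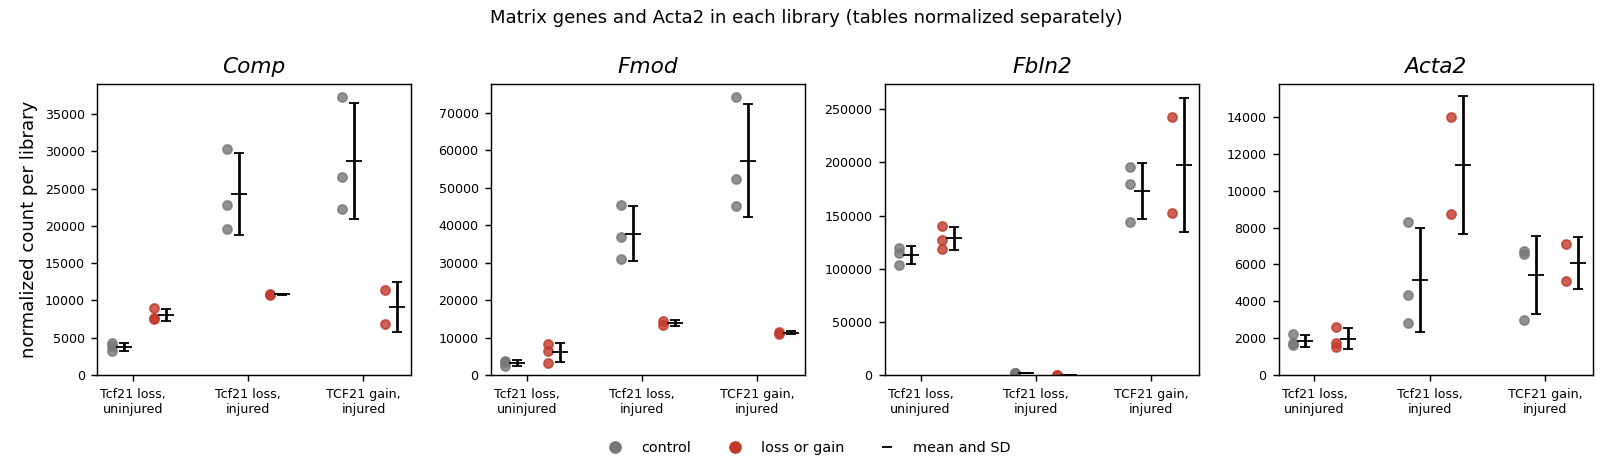
Normalized counts of Comp, Fmod, Fbln2 and Acta2 in each library (points), with group mean and SD; grey, control, and red, loss or gain. Fmod lies lower in both injured comparisons, and Fbln2 lies near the bottom of its axis in the injured loss table, controls included.

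More genes passed in both loss comparisons than independent calls would give. Of 14130 genes tested in both loss comparisons, 43 passed in both and in the same direction (14 higher, 29 lower), where independent calls would give 2.39, and 0 passed in opposite directions, where independent calls would give 2.24. Tcf21 itself, the deleted gene, is among the 29 lower ones. Gabra3, Xdh, Stbd1 (17.8-fold lower without injury) and H2-Bl (-3.99 on the log2 scale without injury, or -4.52 to -3.33 with 1 library left out) were lower in both, and Erlec1, Pim1 and Adat2 were higher in both. Adat2 lies within 10 Mb of Tcf21, and 23.7% of the 38 shared genes with a known position, Tcf21 left out, lie within 1 Mb of another. Across genes, which are not independent replicates, fold changes of the 2 comparisons had Pearson's r = 0.386 and Spearman's rho = 0.273. The genes higher without injury were higher in 197 of 240 cases after infusion (median 0.27, camera adjusted p = 3.52e-17, and adjusted p = 0.0552 with an estimated correlation). The lower ones were lower in 247 of 290 (median -0.32, adjusted p = 9.42e-22, and 0.0552 as adjusted p with an estimated correlation). With the 100 genes of smallest p in each direction the medians were 0.44 and -0.64, each at adjusted p = 0.0459 with an estimated correlation.

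The effect of loss differed between the injured and uninjured comparisons for 21 of 14130 genes (limma interaction, 7 more positive and 14 more negative after infusion). The injured and uninjured libraries lie in separate tables, so injury cannot be told apart from a difference between the tables. For Comp the effect after infusion minus that without injury was -2.24, SE 0.230, adjusted p = 0.00157, Comp having risen without injury and shown a log2 fold change of -1.14 with it. Cspg4 differed by 1.62, SE 0.237, adjusted p = 0.0243, from -1.78 without injury to -0.16 after infusion. Mcm6 differed by -1.55, SE 0.137, adjusted p = 0.000722 and Cd74 by -2.53, SE 0.402, adjusted p = 0.0389. With 1 library left out at a time, Cd74 was not past the test in 8 of 11 fits and Cspg4 in 6 of 11, while Comp and Mcm6 passed in each. 4 of the 21 genes (Fbln2 and, chosen after their values were seen, Mllt6, Gm6139 and Atp6v0c-ps2) are held in the injured loss table at a level over 8-fold apart from one that the other tables share, where 0.276 would be expected. The other 17 passed when all such genes were left out. The count was 13 and 12 without uninjured control 2 or 3, 32 without uninjured deleted library 1 and 57 without injured deleted library 1.

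Fold changes of loss and gain of TCF21 during infusion showed no clear relation across genes. These had r = 0.0346 and rho = 0.136 over 14319 genes, and r turned to -0.0739, -0.0297 and -0.0350 without loss control 1, deleted library 2 or gain control 3. Yet 13 genes passed in opposite directions, where independent calls would give 2.37, among them Tcf21 itself and Adamtsl2, and 2 passed in the same direction, where 2.90 would be expected. These 2 were Ccnd1, higher in both, and Fmod, lower in both. The genes that were higher or lower after loss with injury were not past the test as sets with gain (camera adjusted p = 0.254 and 0.295). The loss and gain arms also differ in the Cre line, which switches on the sorted reporter, and lie in separately normalized tables.

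Of the 3 pairs of comparisons, setting loss without injury against gain with injury was added after the data were examined. These groups differ in injury and in the Cre line, which also switches on the sorted reporter, as well as in TCF21. Here 40 genes passed in opposite directions, where independent calls would give 10.98, and 18 in the same direction, where 11.7 would be expected. Tcf21 itself is among the 40. Comp, Cytl1, Col8a2, Clu, Ifi27 and Il33 were higher with loss without injury and lower with gain, and so was the LIM protein gene Pdlim4 (8.05-fold higher with loss, 3.02-fold lower with gain). None of these was among the genes that passed in opposite directions in loss and gain during infusion. After loss with injury Comp lay lower, as it did with gain (log2 fold change -1.14 and -1.67), though after loss it missed the threshold (limma adjusted p = 0.0534). Meox1 rose in both, and Hmga1b, which has a near-identical relative and is therefore uncertain, was higher in both (6.53 on the log2 scale with loss, or 5.81 to 7.14 with 1 library left out). Over all 14673 shared genes r was -0.0731 and rho -0.0922. The genes higher with loss lay lower with gain in 138 of 241 cases (median -0.040, camera adjusted p = 0.0151, and adjusted p = 0.165 with an estimated correlation). For the 100 higher genes of smallest p this was 57 of 93 tested (median -0.14, adjusted p = 0.00366, and 0.0459 with an estimated correlation). The genes lower with loss were not past the test with gain, with 155 of 302 higher (median 0.010, adjusted p = 0.406). Of the 100 lower genes of smallest p 59 lay lower with gain too (median -0.075, adjusted p = 0.507).

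**Figure D4:**
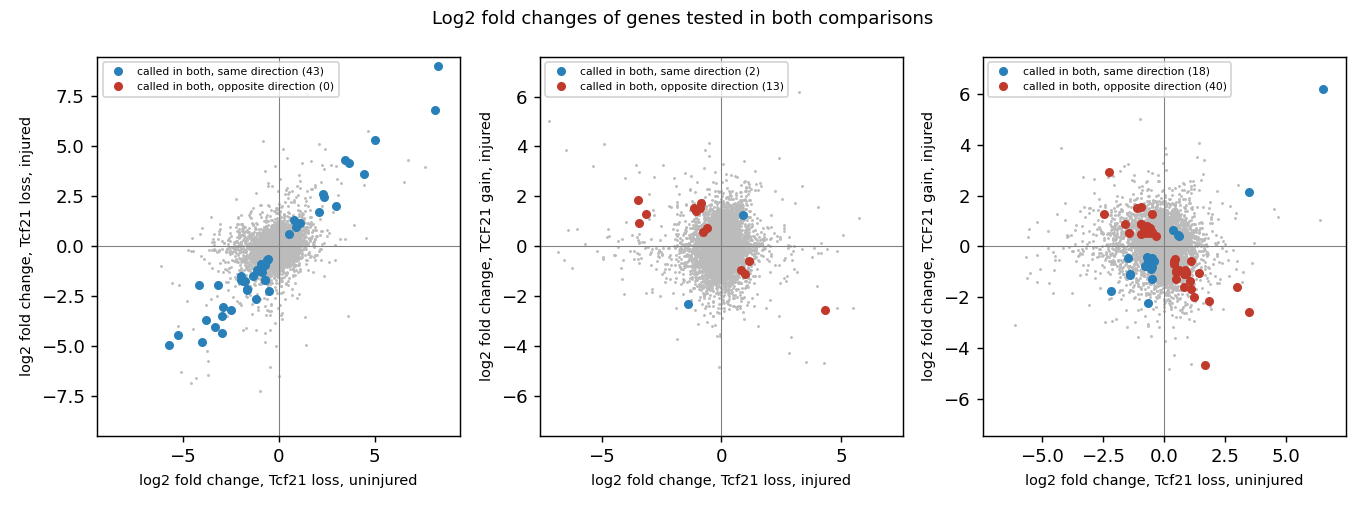
Log2 fold change of each gene in 1 comparison against another (grey), with genes past the threshold in both coloured blue for the same direction and red for opposite directions. Blue points number 43, 2 and 18 and red ones 0, 13 and 40 from left to right.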

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

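The interaction test was planned. Chosen after the results were seen were Mllt6, Gm6139 and Atp6v0c-ps2, the comparison of levels across tables, and the omission of genes at unlike levels. The effect of Tcf21 loss differed between the injured and uninjured comparisons for 8 of the genes named in the text. Since these lie in separate tables, an effect of injury cannot be told apart from a difference between the tables. The effect after infusion minus that without injury, on the log2 scale, was -2.24 for Comp, 1.62 for Cspg4, -1.55 for Mcm6, -2.53 for Cd74, -3.51 for Fbln2, 4.62 for Mllt6, -6.51 for Gm6139 and -6.24 for Atp6v0c-ps2. The injured loss table holds the last 4 of these far from their level in the other tables, controls included, so that their differences compare unlike values. The control means of Fbln2 were 1912 in that table and 112573 in the uninjured one. Comp, Cspg4, Mcm6 and Cd74 are not among the genes at unlike levels across tables, and each passed when those genes were left out. With 1 library left out at a time, Cd74 was not past the test in 8 of 11 fits, Cspg4 in 6 of 11 and Atp6v0c-ps2 in 5 of 11 (-7.03 to -5.50), and the others passed in each fit that tested them.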

How the results depend on the processing

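Left out because they need whole reads, the edgeR and DESeq2 alternatives were not run. The limit to named protein-coding genes, camera without a variance trend, the match of renamed list members, the omission of genes at unlike levels across tables, and the loss sets tested without injury against gain were chosen after the results were seen. Counts of changed genes (loss uninjured, loss injured, gain, in this order) were 94, 72 and 25 without a variance trend, 949, 308 and 1013 with library weights, and 166, 109 and 331 with an absolute log2 fold change of at least 1. With named protein-coding genes only they were 619, 47 and 647. With an estimated correlation 0 lists passed in each comparison. Leaving out 1 library at a time gave 88 to 891, 32 to 175 and 124 to 821 genes, 8 to 13, 11 to 19 and 9 to 18 lists, and 12 to 57 interaction genes. Where this leaves 1 library in a group, it is assumed to vary like the others. Without the genes at unlike levels across tables, the injured loss comparison gave 138 genes and 16 lists, and the interaction 17 genes. The other pseudocounts, filters and scalings and the robust variances kept the gene counts within 1.5 times. Of these, list counts were run only with a pseudocount of 5 and TMM scaling, and the interaction was not run with robust variances or without a filter; what was run stayed within 1.5 times. Genes with means under the filter were not tested.

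Same-numbered libraries had correlations of deviations from their group means of -0.0538 to 0.176, and other pairs of -0.230 to 0.230. The deviations of 2 libraries in a group mirror each other, so these values cannot tell whether the replicate numbers mark a pairing. With the replicate block the counts were 227, 1462 and 1842. In the injured loss and gain comparisons the block leaves control 3 without a partner, so control 3 does not enter those fold changes.

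The correlation of loss fold changes with and without injury was 0.415 with a pseudocount of 5, 0.524 for means of at least 50 and 0.309 to 0.402 with 1 library left out. That of loss and gain was -0.0739 to 0.104 with 1 library left out and reversed to -0.0739, -0.0297 and -0.0350. Loss sets from uninjured hearts missed the threshold with an estimated correlation at the same medians (0.27 and -0.32 after infusion, -0.040 for the higher set with gain), whereas the 100 genes of smallest p passed it (adjusted p = 0.0459; medians 0.44, -0.64 and -0.14). The 100 lower with loss reversed to -0.075 with gain, not past the test either way. The cell cycle list after injured loss reversed in camera's direction without control 1 or deleted library 2, its median being 0.025 to 0.82 with 1 library left out. Genes not past the threshold whose sign reversed were Acta2 in loss without injury (-0.17 to 0.22 with 1 library left out, -0.041 with library weights), Col1a1 in loss without injury (-0.044 to 0.14 with 1 library left out, -0.044 with quantile normalization), Acta2 in gain (-0.15 to 0.48 with 1 library left out, -0.15 with the replicate block), Col1a1 in gain (0.17 with quantile normalization), Postn in gain (-0.15 to 0.17 with 1 library left out, -0.049 with library weights, -0.15 with the replicate block). The cause was not tested for any of these.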

Other observations

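With TCF21 gain during infusion the TGF-beta signalling list was not past camera, with 3 risen, 6 fallen and 22 of 31 tested members not past the test (adjusted over the list alone, 4 risen and 8 fallen), at camera adjusted p = 0.239, and adjusted p = 0.517 with an estimated correlation. Of single genes, the TGF-beta target Pmepa1 rose 3.26-fold (13128 ± 746 against 4064 ± 767 normalized counts, SD, n = 2 and 3, log2 fold change 1.71, SE 0.148, adjusted p = 0.00446) and the inhibitory Smad6 1.84-fold, whereas the NADPH oxidase Nox4 was 1.73-fold lower and the decoy receptor Bambi 1.79-fold lower. The inhibitors of helix-loop-helix factors Id1, Id2 and Id4 rose 2.29-fold, 1.78-fold and 2.503-fold, and the transcription factor Snai1 1.87-fold. Of the mesenchymal and cardiac transcription factors, the list that holds these, 6 of 41 tested members rose and 1 fell (adjusted over the list alone, 8 and 2), and the list was not past camera (adjusted p = 0.355). The serum response factor gene Srf rose 1.48-fold and the LIM protein gene Csrp1 1.87-fold. Of the targets of SRF, MRTF and YAP, 4 of 22 tested members rose and 0 fell (adjusted over the list alone, 4 and 3), and the list was not past camera (adjusted p = 0.0995). Circadian clock genes fell as a list, with 0 risen, 3 fallen and 14 of 17 tested members not past the test (adjusted over the list alone, 0 risen and 4 fallen), and Dbp and Nr1d1 were 3.29-fold and 2.70-fold lower (camera adjusted p = 0.00362, and adjusted p = 0.517 with an estimated correlation). Srf was not past the test in 4 of 5 fits with 1 library left out. The clock list was not past camera without control 3 (median -0.34) or gain library 2 (-0.39). This list also fell after injured loss, at a median of -0.47 (-0.68 to -0.24 with 1 library left out), with 0 single members past the test (camera adjusted p = 0.00125, and adjusted p = 0.547 with an estimated correlation).

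In uninjured hearts the transcription factor genes Heyl, Sox9 and Zeb1 were 1.78-fold, 1.39-fold and 1.303-fold lower after loss of Tcf21. Of their list, 1 of 41 tested members rose and 4 fell (adjusted over the list alone, 1 and 5), and the list was not past camera (adjusted p = 0.223). The immediate early gene Nr4a1 was 1.81-fold lower. Of the endothelial markers, Plvap and Aqp1 rose 2.64-fold and 2.17-fold, and Cd93 fell to 0.309 ± 0.535 from 20.6 ± 6.95 normalized counts. On the endothelial list 2 of 13 tested members rose and 1 fell (adjusted over the list alone, 2 and 5), and the list was not past camera (adjusted p = 0.471). The fibroblast genes Pi16 and Clec3b rose 1.48-fold and 1.47-fold. Of the resting fibroblast genes, 2 of 32 tested members rose and 0 fell (adjusted over the list alone, 3 and 0), and the list was not past camera (adjusted p = 0.223). With 1 library left out, Zeb1 was not past the test in 5 of 6 fits, and Aqp1, Pi16 and Sox9 were not in 4 of 6 each.

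Of the tests below, those of other splits of the libraries and of transcript length were chosen before their results were seen, except the split counts of lists for the injured loss and gain comparisons, and the other tests were chosen after. In the uninjured loss comparison 557 genes passed under the real split (1 of 10 splits gave as many) and at most 1 under another. The real split gave 135 genes and the highest other split 2 in injured loss, and 637 and 0 in gain. For lists the real and the highest other split gave 10 and 12, 16 and 20, and 14 and 18, and 5, 5 and 4 of the 10 splits gave as many lists. With 10 splits a share under 0.05 cannot be reached, since the smallest is 0.1, so the gene counts could not exclude chance. The list counts did not stand apart from those of other splits, whatever the smallest share. For the correlation between the loss comparisons, 1 of 100 pairs of splits, the real one, gave an r as large in size, the highest other being 0.340. Fewer than 0.05 of the pairs was the mark set beforehand, so by this rule the values argue against chance. The pairs reuse the same libraries and are not independent, so this is not a firm exclusion. Without injured deleted library 1, a smaller set than the splits used, r was 0.309. For the correlation between injured loss and gain, 87 of 100 pairs gave an r as large in size (real 0.0346, highest other 0.373). For that correlation chance was not excluded.

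The genes called in both loss comparisons in the same direction may in part reflect sequence variants carried along with the floxed allele, or variants or copies elsewhere in the genome. Of 38 such genes with a known position, Tcf21 left out, 5.26% lay within 10 Mb of Tcf21 (Adat2 and, chosen after its values were seen, Hebp2, not past the test in 6 of 6 and 4 of 5 fits with 1 library left out), where the middle 95% of random draws gave 0% to 2.63%. Near another gene of the group, within 1 Mb, lay 23.7%, against 5.26% as the median and 18.4% as the upper bound of random draws. The second value goes with variants or sequence copies for part of the genes, while the first rests on 2 genes, of which Adat2 too was not past the test in 3 of 5 injured fits. Whether loss of Tcf21 itself moved the group cannot be told apart from these, since of the 38 shared genes tested with gain, with or without a known position, 20 moved opposite, where random draws gave 13 to 25. Neighbouring genes that answer loss of Tcf21 together would also raise the share within 1 Mb of another. This was not tested.

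The small rise of oxidative phosphorylation genes in uninjured loss was tested against technical sources. Random lists matched on transcript length and level had medians of -0.025 to 0.14, under the list's 0.19. They were drawn gene by gene, without the correlation among the list's members (estimated at 0.20), so their range may be too narrow. A length trend as a part or the whole of the rise was therefore not excluded. RNA from cardiomyocytes, which the sort for EGFP is meant to remove, was argued against by a median of -0.24 over 19 cardiomyocyte markers. Cardiomyocyte marker RNA was still counted after the sort. Tnnt2, chosen after its values were seen as the most abundant but Atp2a2, was 129 ± 37.6 against 163 ± 25.9 normalized counts. A response to loss of Tcf21 stays open as a hypothesis.

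The higher cell cycle genes with TCF21 gain did not rest on 1 library, since the lowest median with a library left out was 0.81, without control 3. Cycling myeloid cells, which the same sort is meant to remove, were argued against by summed myeloid marker counts. These rose by at most 0.125 of the summed rise of cell cycle genes in a gain library. Myeloid marker RNA was still counted after the sort. The most abundant marker, Lyz2 (chosen after its values were seen), lay at 1962 ± 1144 against 1064 ± 229.7 normalized counts. Unequal cycling of the control fibroblasts, whose medians ranged from -0.92 to 0.72, and an effect of TCF21 stay open and were not tested.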
